A study of Arabidopsis thaliana with 9 samples.

How the data were processed

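RNA from rosettes of Arabidopsis thaliana Col-0, the overexpressing line PP2-A5oe and the mutant line pp2-a5 was sequenced in 9 libraries, 3 biological replicates per group, all under the control treatment. The labels name the rosette as source, while the extraction protocol speaks of seedlings at an age of 3 weeks. Per the labels, RNA was isolated on RNeasy columns and treated with DNase, polyadenylated RNA was enriched on oligo(dT) beads, and cDNA was made from fragments with random hexamers. The deposited table holds raw counts per locus, made by the authors against the TAIR10 genome; the aligner, the counting tool, the gene models and the strand setting are not given in the sources used here. The table has 22449 entries for 22155 loci, of which 294 loci have 2 entries, and each entry has at least 1 count in some library. Counts of entries with the same locus name were summed. Names, positions and transcript numbers came from the TAIR10.1 annotation, which matched 21952 loci and left 203 without a match. The counting unit for genes with several transcripts is not stated, so values of such genes are less certain and are marked where they are named.

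Total counts ranged from 5408847 to 6196722 per library. At these totals, 3 counts over the 3 libraries of a group, the floor for folds against a group at 0 counts, were 0.171 CPM in Col-0 and 0.161 CPM in pp2-a5 (CPM, counts scaled to a fixed library total). Counting intervals are exact binomial at 95%, and intervals and floors cover counting error only. With groups of 3, an exact permutation test of 1 gene could not go below p = 0.1, so tests came from a model fitted across all genes.

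Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0; tables and plots were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Loci with low counts were removed by filterByExpr (minimum count 10, minimum total count 15), which left 13975 loci holding 99.76% of all counts. Libraries were scaled by TMM. All 9 libraries were fitted in 1 quasi-likelihood model with a mean per group and robust dispersions, with 6 residual degrees of freedom and a biological coefficient of variation of 6.89%. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 within a comparison, with no fold threshold and no shrinkage. The 4 comparisons were PP2-A5oe against Col-0, pp2-a5 against Col-0, PP2-A5oe against pp2-a5, and the mean of both lines against Col-0. The p-values measure only the spread between these samples, since the labels do not say how the biological replicates were grown or harvested.

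The 34 gene lists covered hormones, glucosinolates, immunity, stress, nutrients, growth, the PP2-A lectin family and markers of other tissues; 33 had the required 3 tested members, and the list of seed storage genes did not. Lists were tested with camera at a preset correlation of 0.01 and, as alternatives, with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. With an estimated correlation, camera also used the 6 residual degrees of freedom of the fit, in place of a number near that of all genes. A list can therefore be lost there without an estimated correlation above 0.01. Camera compares a list with all other genes, while fry asks whether a list's genes move one way on balance, or in either direction (mixed), and compares the list with no other genes. Comparisons, tests, lists, the rule for named genes and the alternatives, apart from 3 added later, were fixed before the data were examined. By that rule, the text names the 10 largest rises and the 10 largest falls in each line against Col-0, and 5 in each direction in the other comparisons. These genes needed an adjusted p under 0.05, a mean of at least 1 CPM in the higher group and no overlap of replicates. From each list up to 3 called members with the smallest adjusted p were named, or up to 2 of the most abundant where none was called, and the 10 annotated genes on each side of PP2-A5 were examined. Genes named outside the rule are marked as chosen after their values were seen.

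Alternatives were RLE and upper-quartile scaling, DESeq2, limma-voom, no filter, a stricter filter (10 CPM in at least 3 libraries), fits of only the groups compared, the replicate number as a block, a 2-fold threshold, an adjusted p under 0.01, removal of organelle genes and leaving out each of the 9 libraries. The 3 added after seeing the data were genes with 1 annotated transcript only, entries of a locus kept separate, and a fit without the pair of libraries with the highest mitochondrial share. The overlap between the lines was compared with 50 simulated data sets of unchanged groups that shared their controls. Tested on simulated data with 50 changed genes per fold, the fit recovered 32%, 72%, 76% and 96% of genes changed 1.25-, 1.5-, 2- and 4-fold in PP2-A5oe against Col-0, with 9 unchanged genes called. The transcript of PP2-A5 itself (AT1G65390) was not analysed here, so the planned check of the labels by that gene and its alternatives were not run.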

Results

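Polyadenylated RNA was counted per locus in rosettes of Col-0, of PP2-A5oe, which overexpresses the gene for PP2-A5, a protein that joins a TIR domain to a lectin domain, and of pp2-a5, a mutant of that gene. Each group had 3 biological replicates. Total counts were 6196722, 6048575 and 5408847 in Col-0 replicates 1 to 3, 6182508, 5703364 and 5799277 in PP2-A5oe, and 6122079, 5956315 and 6191397 in pp2-a5. The 10 most abundant loci took 7.55% to 8.53% of the counts. Chloroplast transcripts made up 2.49% to 2.78% of the counts, and mitochondrial transcripts 0.0741% to 0.0878% except in Col-0 replicate 3 (0.178%) and PP2-A5oe replicate 2 (0.132%). On the first principal component, with 40.4% of the variance, and the second, with 23.7%, the 3 groups lay apart. On the third, with 9.56%, Col-0 replicate 3 lay at -23.9, away from replicates 1 (8.44) and 2 (14.8). Its chi-square per degree of freedom against them was 5.53 and 6.71, while the other pairs within a group had 1.64 to 3.5. A value after ± is the SD for CPM and the standard error for a log2 fold change, with n = 3 per group. Each called gene that is named for a single line or between the lines had all 3 replicates of one group above all 3 of the other. For the largest rises and falls this was a condition of being named, and list members were picked by the smallest adjusted p.

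**Figure D1:**
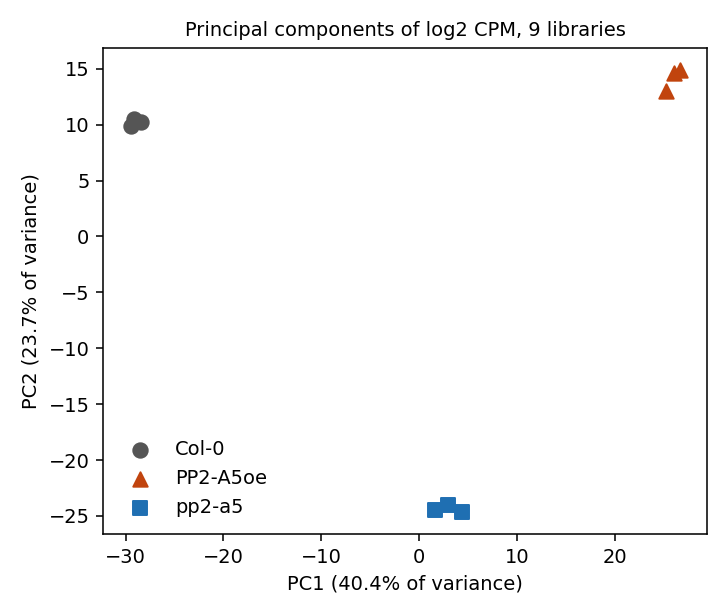
Scores of the 9 libraries on the first principal component (x axis, 40.4% of the variance) and the second (y axis, 23.7%) of log2 CPM; points are libraries, with a colour and shape per group. The 3 groups form separate clusters of 3 libraries.

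The PP2-A5 transcript, on chromosome 1 from 24292372 to 24294740 (TAIR10.1, 3 annotated transcripts), was not analysed here. Of the 20 annotated genes closest to it, 6 were tested. AT1G65370 was lower in both lines, with 62.8 ± 3.54 CPM in Col-0, 45.3 ± 5.58 CPM in PP2-A5oe and 49.1 ± 1.49 CPM in pp2-a5. Its log2 fold change was -0.47 ± 0.09 in PP2-A5oe (adjusted p = 0.000102) and -0.36 ± 0.09 in pp2-a5 (adjusted p = 0.00279). The other 5, UBQ13, CLV2, ABCI13, NPQ7 and ARI8, were not called in either line.

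In PP2-A5oe rosettes, genes that respond within minutes to touch and wounding stood far above their Col-0 level: 17 of 17 tested members of this list rose, with a median log2 fold change of 2.77. CAF1a, a deadenylase of the mRNA decay machinery, went from 17.38 ± 3.42 to 287.7 ± 18.7 CPM, a log2 fold change of 4.06 ± 0.10. The zinc finger repressor ZAT10 (STZ) went from 25.2 ± 1.76 to 342.4 ± 8.13 CPM, a log2 fold change of 3.77 ± 0.08. Cold-response genes rose with them (9 of 11, median 1.18), among them CBF2, an activator of cold-regulated genes, from 2.70 ± 0.825 to 50.1 ± 2.03 CPM. Genes induced by sulphur starvation also rose (7 of 8, median 1.04), while genes of aliphatic glucosinolate biosynthesis fell (10 of 20, median -0.32).

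The comparison of PP2-A5oe with Col-0 asked what differed in the overexpressing line, and it called 3496 genes, 2027 higher and 1469 lower. The labels name no further overexpressing or mutant line. An effect of the gene therefore cannot be told apart from other differences between these plants, here or in the comparisons below. With upper-quartile scaling the calls numbered 3838, of which 1769 were higher and 2069 lower, so the share of higher calls depended on the scaling. A 2-fold change was reached by 476 of the higher and 109 of the lower genes. In 36.8% of tested genes the replicates of both groups did not overlap, where chance gives 10%. The dicarboxylate carrier gene DIC2 (chromosome 4, 12686459 to 12687650) went from 16.9 ± 2.88 to 469 ± 7.49 CPM, a log2 fold change of 4.80 ± 0.09 (adjusted p = 8.14e-29). AT1G03240 (chromosome 1, 792222 to 793060) had 0 counts in Col-0 and 204 in PP2-A5oe, at least 68.6-fold higher against the floor of 3 counts over the group. AT5G21960 also had 0 counts in Col-0 and was at least 45.4-fold higher. The small peptide gene RTFL12 rose from 1.07 ± 0.30 to 24.0 ± 3.58 CPM. CBF1 had 3 counts in Col-0 and 162 in PP2-A5oe, a ratio of 54.5 with a counting interval from 18.3 to 267. AT1G26250, AT4G27654, AT2G35290, UMAMIT26 and AT2G32200 had 1 count each in Col-0 and 37 to 48 in PP2-A5oe, with ratios from 37.3 to 48.5 and lower bounds of their counting intervals from 6.30 to 8.29.

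Among the largest falls in PP2-A5oe were RNS1, a secreted ribonuclease, from 3.6 ± 1.54 to 0.351 ± 0.188 CPM (log2 fold change -3.28 ± 0.49, adjusted p = 2.71e-06), and ELI3-2, from 9.16 ± 1.32 to 0.927 ± 0.444 CPM (-3.28 ± 0.30, adjusted p = 9.67e-11). The glutathione transferase genes GSTU3 (-3.07 ± 0.35) and GSTU11 (-2.77 ± 0.29) fell, as did the polygalacturonase gene PGAZAT (-2.50 ± 0.34), AT5G49560 (-2.54 ± 0.38), AT5G39520 (-2.34 ± 0.29) and the pseudogene AT4G08093 (-3.19 ± 0.54). CCD8, a gene of strigolactone biosynthesis, fell by 3.02 on the log2 scale, but it has 2 annotated transcripts and overlaps another gene. WRKY75, at -2.34 ± 0.62, was no longer called without the pair of libraries with the highest mitochondrial share.

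The touch and wound list had an adjusted p of 1.9e-148 in PP2-A5oe against Col-0 (0.00027 with an estimated correlation), with 17 members called when adjusted over the list alone. It shares ZAT10 and ZAT12 with the cold list and WRKY33 and WRKY40 with the immune list. The cold list in turn shares LTI30 and RD29A with the abscisic acid list, 2 of the 10 tested members of the latter. The cold list had an adjusted p of 8.81e-28 and 9 higher members adjusted over the list alone; ZAT12 (RHL41) rose by 3.39 ± 0.20 on the log2 scale. Of 21 tested immune receptors and early immune response genes, 12 rose (13 adjusted over the list alone, median 0.40, adjusted p = 2.2e-16). The transcription factor genes WRKY33 (75.6 ± 6.93 to 309.7 ± 11.5 CPM), WRKY53 (8.03 ± 2.32 to 54.4 ± 1.24 CPM) and WRKY40 (5.16 ± 0.811 to 47.3 ± 6.17 CPM) led this list, though each overlaps another gene. The sulphur list had an adjusted p of 1.74e-17 (7 members adjusted over the list alone), with SHM7 at 1.36 ± 0.06 and SDI1 at 1.26 ± 0.07, and APR1, an enzyme gene of sulphate reduction, went from 119 ± 14.6 to 292 ± 2.74 CPM.

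Jasmonate, abscisic acid and clock genes rose in PP2-A5oe as well. In jasmonate biosynthesis and turnover 9 of 17 tested genes rose (9 higher and 2 lower adjusted over the list alone, median 0.58, adjusted p = 6.51e-05); AOC2 rose by 1.01 ± 0.07, LOX4 by 1.72 ± 0.13 and AOS by 0.81 ± 0.06 on the log2 scale. In jasmonate signalling and the MYC branch 7 of 14 rose and 2 fell, the same counts as adjusted over the list alone, with MYC2, a master regulator of jasmonate responses, at 1.60 ± 0.07 and NATA1 at -1.16 ± 0.24. That list passed at an adjusted p of 0.00797, but not with an estimated correlation (adjusted p = 0.0757 with an estimated correlation) or over genes with 1 annotated transcript. Its estimated correlation was 0.01, the same as the preset, and its unadjusted camera p still went from 0.00314 to 0.0252. Of 10 abscisic acid genes 8 rose (8 higher and 1 lower adjusted over the list alone, median 0.67, adjusted p = 3.11e-05), among them NCED3, a key enzyme of abscisic acid synthesis, at 1.63 ± 0.10. Of 12 clock genes 7 rose (8 adjusted over the list alone, median 0.43, adjusted p = 7.93e-06). GI went from 1.53 ± 0.875 to 11.8 ± 1.46 CPM, and RVE1 and PRR7, which have 2 annotated transcripts each, rose by 1.31 ± 0.07 and 1.65 ± 0.14.

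Glucosinolate genes went in 2 directions in PP2-A5oe. Aliphatic biosynthesis genes fell (11 lower adjusted over the list alone, adjusted p = 0.000201), with CYP83A1 at -0.45 ± 0.07 and MAM1, which has 3 annotated transcripts, at -0.52 ± 0.07. Of 14 indolic biosynthesis genes 9 rose (9 adjusted over the list alone, median 0.44, adjusted p = 5.66e-06, but adjusted p = 0.0594 with an estimated correlation), with CYP81F2 at 1.68 ± 0.16, CYP83B1 at 0.66 ± 0.06 and SOT16 at 0.69 ± 0.07. Phenylpropanoid and lignin genes rose in 7 of 11 cases (8 adjusted over the list alone, median 0.34, adjusted p = 0.00139, but adjusted p = 0.165 with an estimated correlation), with PAL1 at 0.58 ± 0.06. Nuclear photosynthesis genes fell in 20 of 34 cases (22 adjusted over the list alone, median -0.17, adjusted p = 0.00163, but adjusted p = 0.543 with an estimated correlation). Among these, LHCB1.4 (LHB1B1) fell from 864 ± 56.3 to 529.6 ± 48.0 CPM, a member of a family of near-identical genes whose reads are hard to assign. Root tissue markers moved with these groups: 4 of 5 rose (5 adjusted over the list alone, median 1.57, adjusted p = 0.00545, but adjusted p = 0.065 with an estimated correlation), LRX1 from 2.80 ± 0.254 to 8.33 ± 1.60 CPM. As the sources speak both of rosettes and of seedlings, a difference in tissue make-up between the groups stays open and was not tested. Salicylic acid genes did not pass in PP2-A5oe (9 of 25 rose and 1 fell, 10 and 2 adjusted over the list alone, median 0.24, adjusted p = 0.076), nor did the jasmonate and ethylene branch (3 of 9 rose and 1 fell, 5 and 1 adjusted over the list alone, adjusted p = 0.187). Phosphate starvation genes (2 of 8 rose and 2 fell, 2 and 3 adjusted over the list alone, adjusted p = 0.585), iron deficiency genes (2 of 6 rose, 3 higher and 1 lower adjusted over the list alone, adjusted p = 0.54) and camalexin genes (1 of 7 rose and 4 fell, 3 and 4 adjusted over the list alone, adjusted p = 0.156) did not pass either. Directional fry, which compares a list with no other genes, did call several of these lists. Its adjusted p was 0.000726 for salicylic acid, 0.00104 for the jasmonate and ethylene branch and 0.00419 for iron genes, all higher. It was 0.0121 for camalexin genes, which were lower, and 0.427 for phosphate genes.

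Of 33 lists 13 passed in this comparison, and the 8 that held with an estimated correlation were touch and wound, cold, sulphur, immune, jasmonate biosynthesis, abscisic acid, clock and aliphatic glucosinolate genes.

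**Figure D2:**
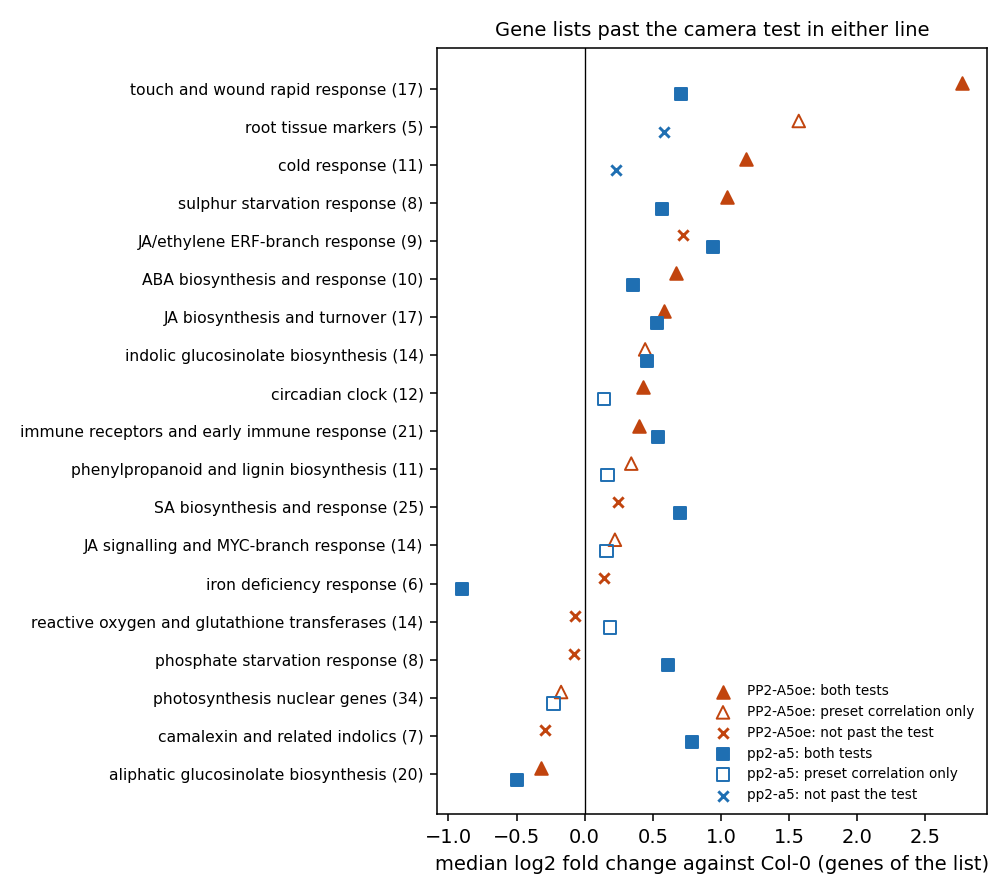
Median log2 fold change against Col-0 (x axis) of the gene lists that passed the camera test in either line (y axis, tested members in brackets), with triangles for PP2-A5oe and squares for pp2-a5; filled symbols passed with preset and estimated correlation, open ones with the preset correlation alone, and crosses did not pass. The touch and wound list lies furthest to the right in PP2-A5oe against Col-0, at 2.77, and the salicylic acid list lies at 0.70 in pp2-a5 against Col-0.

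In pp2-a5 rosettes, genes of salicylic acid biosynthesis and response were higher than in Col-0: 20 of 25 tested members rose, with a median log2 fold change of 0.70. The pathogenesis-related gene PR1, a marker of salicylic acid responses, went from 27.9 ± 1.74 to 109.9 ± 10.6 CPM, a log2 fold change of 1.98 ± 0.09. The defensin gene PDF1.2 (PDF1.2a), a marker of the jasmonate and ethylene branch, went from 1.81 ± 0.877 to 26.2 ± 2.64 CPM, a log2 fold change of 3.87 ± 0.21, although its reads are hard to tell from those of PDF1.2b and PDF1.2c. All 8 tested genes of the phosphate starvation list rose, and 5 of 6 genes of the iron deficiency list fell. Aliphatic glucosinolate biosynthesis genes fell in 12 of 20 cases, with a median of -0.49.

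The comparison of pp2-a5 with Col-0 asked what differed in the mutant line, and it called 2902 genes, 1719 higher and 1183 lower (406 and 65 with a 2-fold change). With upper-quartile scaling 1536 of 3089 were higher and 1553 lower. In 33.7% of tested genes the replicates did not overlap, where chance gives 10%. The pseudogene AT5G35935 (chromosome 5, 14083388 to 14089891) went from 0.335 ± 0.149 CPM in Col-0 to 48.3 ± 3.66 CPM in pp2-a5, a log2 fold change of 7.06 ± 0.23 (adjusted p = 1.49e-21). AT1G26250, which overlaps another gene, had 1 count in Col-0 and 177 in pp2-a5, a ratio of 167 with a counting interval from 29.5 to 6620. PDF1.2b had 2 and 93 counts (ratio 43.8, interval 11.8 to 367), AT1G26240 had 1 and 49 (46.2, 7.90 to 1860), AT5G38910 had 1 and 43 (40.5, 6.89 to 1640) and RHS14 had 2 and 30 (14.1, 3.58 to 122). AACT1, an acyltransferase gene, rose by 3.25 ± 0.21, and PDF1.2c by 3.90 ± 0.51 on the log2 scale. The metacaspase gene MC8 went from 0.941 ± 0.626 to 9.09 ± 0.804 CPM.

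Among the largest falls in pp2-a5, the orphan gene QQS went from 24.5 ± 2.95 to 3.77 ± 0.189 CPM (log2 fold change -2.70 ± 0.16, adjusted p = 5.46e-15), with 3 annotated transcripts. SAG29, a sugar transporter gene linked to senescence, went from 35.8 ± 1.37 to 8.44 ± 1.27 CPM (-2.09 ± 0.13, adjusted p = 9.49e-15). The cold-regulated gene KIN1 fell from 1.94 ± 0.140 to 0.266 ± 0.176 CPM, with reads that are hard to tell from those of its close neighbour KIN2. PP2-A8, a relative of PP2-A5, fell by 2.21 on the log2 scale (standard error 0.43). The pseudogenes AT3G30122 (-2.92 ± 0.40) and AT2G16367 (-2.17 ± 0.44) fell, as did AT2G14247 (-2.42 ± 0.45) and the non-coding AT2G05914 (-2.34 ± 0.31), which overlap other genes. Counts of the pseudogene AT4G08093 were 49 in Col-0 and 1 in pp2-a5, a ratio of 52.0 with an interval from 8.91 to 2100. MRD1, with 2 transcripts and an overlapping gene, had 35 and 1 counts, a ratio of 37.2 with an interval from 6.25 to 1510.

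The salicylic acid list had an adjusted p of 1.03e-31 in pp2-a5 against Col-0 (22 higher adjusted over the list alone), with DMR6, a salicylic acid hydroxylase gene, at 1.81 ± 0.07 and WAK1 at 1.39 ± 0.07. Of 21 immune genes 11 rose (11 adjusted over the list alone, median 0.54, adjusted p = 1.99e-17), with WRKY53 at 3.14 ± 0.13 and SOBIR1, a co-receptor of immune receptors, at 1.04 ± 0.07. In the jasmonate and ethylene branch 6 of 9 rose (9 adjusted over the list alone, median 0.94, adjusted p = 3.88e-13), with PDF1.3 at 3.04 ± 0.33. Jasmonate biosynthesis genes rose in 10 of 17 cases (10 adjusted over the list alone, median 0.53, adjusted p = 8.04e-07), with LOX4 at 1.62 ± 0.13 and AOC1 at 0.83 ± 0.08. The touch and wound genes rose in 13 of 17 cases (14 adjusted over the list alone, median 0.71, adjusted p = 2.92e-13), with WRKY40 at 1.93 ± 0.17 and WRKY33 at 1.63 ± 0.07. Of 7 camalexin genes 5 rose and 1 fell (6 higher and 1 lower adjusted over the list alone, median 0.79, adjusted p = 0.000412), with GSTF7 at 1.46 ± 0.09 and CYP71A13, a camalexin synthesis gene that overlaps another gene, at -1.41 ± 0.10.

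Nutrient lists changed in pp2-a5. The 8 phosphate starvation genes (8 adjusted over the list alone) had a median of 0.61 and an adjusted p of 6.35e-12; SPX1, a phosphate sensor gene, went from 67.0 ± 1.21 to 178.6 ± 14.5 CPM, and PAP17 rose by 1.15 ± 0.08. Iron deficiency genes fell (5 adjusted over the list alone, median -0.90, adjusted p = 7.06e-05), with the peptide gene IMA2 (AT1G47395) at -1.65 ± 0.28 and NAS4 at -0.53 ± 0.08. Sulphur starvation genes rose in 7 of 8 cases (7 adjusted over the list alone, median 0.57, adjusted p = 1.63e-07), with SHM7 at 0.78 ± 0.06. Aliphatic glucosinolate genes (14 lower and 1 higher adjusted over the list alone, adjusted p = 2.37e-13) included their regulator MYB29, which fell from 35.6 ± 1.41 to 12.2 ± 2.25 CPM, and IPMI2, at -0.90 ± 0.09. Indolic glucosinolate genes rose in 8 of 14 cases and 1 fell, as adjusted over the list alone (median 0.45, adjusted p = 2.22e-07), with CYP81F2 at 1.78 ± 0.15. Abscisic acid genes rose in 5 of 10 cases and 1 fell (6 higher and 1 lower adjusted over the list alone, median 0.36, adjusted p = 0.00257), a call that was lost over genes with 1 annotated transcript.

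Other lists passed in pp2-a5 with the preset correlation alone. Nuclear photosynthesis genes fell in 25 of 34 cases (27 lower and 1 higher adjusted over the list alone, median -0.23, adjusted p = 1.5e-07, but adjusted p = 0.268 with an estimated correlation), with LHCB1.4 at -0.80 ± 0.07. Genes of reactive oxygen and glutathione transferases rose in 6 of 14 cases and 3 fell (8 higher and 3 lower adjusted over the list alone, median 0.19, adjusted p = 0.000361, but adjusted p = 0.242 with an estimated correlation), with GSTF2 and its close relative GSTF3 at 1.35 ± 0.06 and 1.44 ± 0.10. Clock genes rose in 5 of 12 cases (6 higher and 3 lower adjusted over the list alone, median 0.14, adjusted p = 0.00104, but adjusted p = 0.0714 with an estimated correlation). Phenylpropanoid genes rose in 5 of 11 cases and 1 fell, also adjusted over the list alone (median 0.17, adjusted p = 0.043, but adjusted p = 0.296 with an estimated correlation). Jasmonate signalling genes rose in 5 of 14 cases (5 higher and 1 lower adjusted over the list alone, median 0.16, adjusted p = 0.0444, but adjusted p = 0.143 with an estimated correlation). The phenylpropanoid and jasmonate signalling calls also ended with upper-quartile scaling and with the stricter filter, and the clock call over genes with 1 annotated transcript. The other 12 of the 17 lists that passed held with an estimated correlation. Cold genes did not pass (2 of 11 rose and 2 fell, adjusted over the list alone the same, median 0.23, adjusted p = 0.524). Root tissue markers had 0 of 5 members called by edgeR, and 0 at an unadjusted p under 0.05, by DESeq2 or by limma-voom. PYK10 had 245 ± 30.6 CPM in Col-0 and 243 ± 11.5 CPM in pp2-a5. The median of the 5 root markers was nonetheless 0.58. Their list did not pass with camera (adjusted p = 0.55) but was higher with directional fry (adjusted p = 0.0195).

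**Figure D3:**
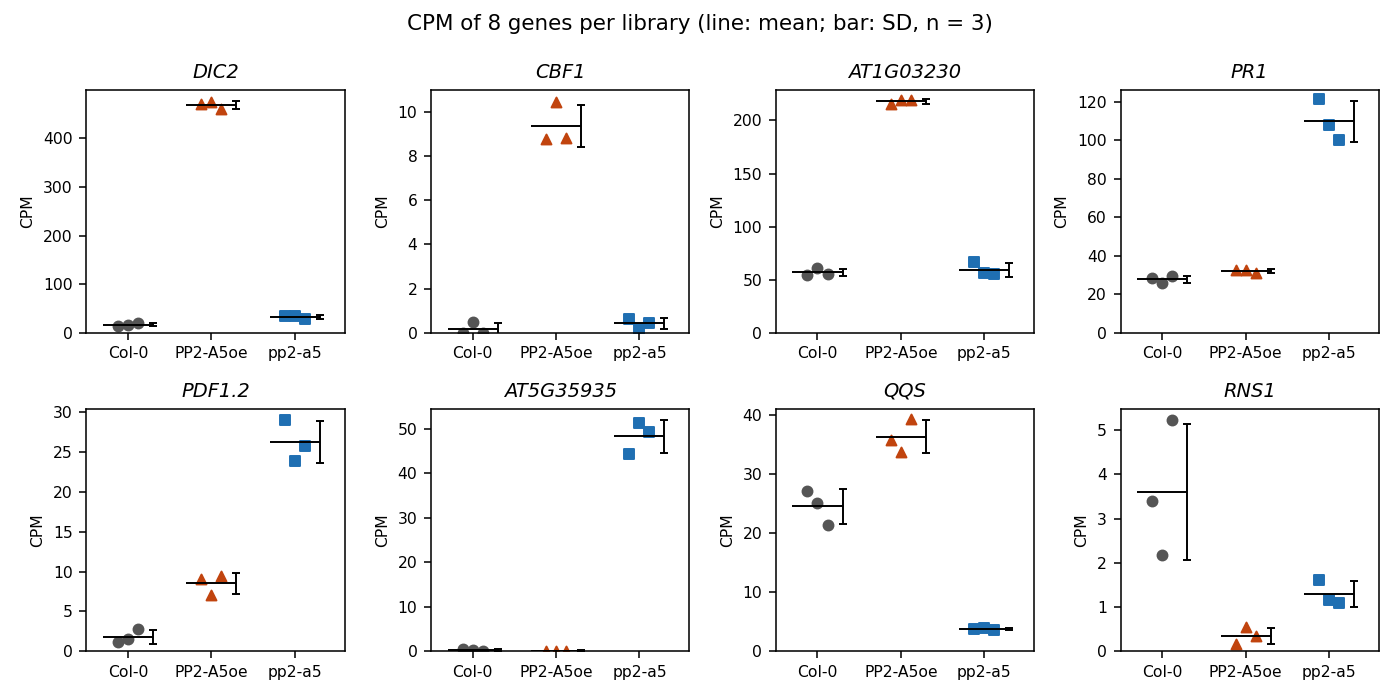
CPM per library (y axis) by group (x axis) for DIC2, CBF1, AT1G03230, PR1, PDF1.2, AT5G35935, QQS and RNS1; points are libraries, lines are group means and bars the SD (n = 3), and AT1G03230 was chosen after its values were seen. DIC2 reached 469 CPM in PP2-A5oe and PR1 reached 109.9 CPM in pp2-a5.

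Between the lines, touch, wound and cold genes were higher in PP2-A5oe, and salicylic acid, phosphate starvation and camalexin genes were higher in pp2-a5. Of 17 touch and wound genes 15 were higher in PP2-A5oe, with a median log2 fold change of 1.79, and CAF1a differed by 3.85 ± 0.09. Of 25 salicylic acid genes 18 were lower in PP2-A5oe, with a median of -0.74, and PR1 stood at 32.1 ± 1.03 CPM in PP2-A5oe and 109.9 ± 10.6 CPM in pp2-a5 (log2 fold change -1.77 ± 0.09). All 8 phosphate starvation genes were lower in PP2-A5oe and all 6 iron deficiency genes were higher.

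This comparison asked where the overexpressing and the mutant line differed, and it called 1769 genes, 1007 higher and 762 lower in PP2-A5oe (206 and 189 with a 2-fold change). In 28.4% of tested genes the replicates did not overlap, where chance gives 10%. The 5 largest rises in PP2-A5oe included AT1G03240 (204 against 1 counts, ratio 219, interval 38.8 to 8680) and AT3G09870, with 0 counts in pp2-a5 and at least 15.4-fold higher in PP2-A5oe. MRD1 had 42 against 1 counts (ratio 45.0, interval 7.65 to 1820), and CBF1 differed by 4.38 ± 0.36. ILA, with 3 transcripts and an overlapping gene, stood at 16.7 ± 0.892 CPM in PP2-A5oe, 0.536 ± 0.0775 CPM in pp2-a5 and 0.971 ± 0.186 CPM in Col-0. On the other side, AT5G35935 had 899 counts in pp2-a5 and 2 in PP2-A5oe, a ratio of 419 with an interval from 116 to 3470. PDF1.3 (-2.92 ± 0.32), ELI3-2 (-2.92 ± 0.31), AT5G49560 (-2.82 ± 0.36) and PGAZAT (-2.75 ± 0.33) were lower in PP2-A5oe.

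List tests between the lines passed for 17 lists, and 8 of them held with an estimated correlation. Of these 8, touch and wound genes (16 higher adjusted over the list alone, adjusted p = 9.28e-149) and cold genes (10 of 11 higher, 10 adjusted over the list alone, adjusted p = 9.05e-43) were higher in PP2-A5oe. Iron genes (6 adjusted over the list alone, adjusted p = 1.89e-07) and sulphur genes (7 of 8 higher, 7 adjusted over the list alone, adjusted p = 1.86e-07) were also higher. Salicylic acid genes (20 adjusted over the list alone, adjusted p = 7.9e-23) and phosphate genes (8 adjusted over the list alone, adjusted p = 5.54e-16) were lower. Lower as well were the jasmonate and ethylene branch (7 of 9 lower, 7 lower and 1 higher adjusted over the list alone, adjusted p = 6.19e-09) and camalexin genes (5 of 7 lower and 1 higher, 6 and 1 adjusted over the list alone, adjusted p = 3.48e-09). SPX3, a regulator of phosphate signalling, differed by -2.49 ± 0.24, BTS, a regulator of iron uptake, by 0.53 ± 0.07, SDI1 by 0.65 ± 0.07, and CYP71A12, a gene of camalexin synthesis, by -1.96 ± 0.14. Glutathione transferase and reactive oxygen genes were lower in 7 of 14 cases (7 lower and 1 higher adjusted over the list alone, adjusted p = 2.65e-05, but adjusted p = 0.19 with an estimated correlation). Root tissue markers were higher in PP2-A5oe in 4 of 5 cases (4 adjusted over the list alone, adjusted p = 0.00445, but adjusted p = 0.0603 with an estimated correlation), with PYK10 at 320 ± 7.09 CPM against 243 ± 11.5 CPM. Aliphatic glucosinolate genes were higher in 7 of 20 cases and lower in 1 (11 higher and 1 lower adjusted over the list alone, adjusted p = 0.00963, but adjusted p = 0.0603 with an estimated correlation), a call lost over genes with 1 annotated transcript.

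A further 6 calls between the lines had adjusted p from 0.0346 to 0.0499, and each was lost with an estimated correlation and without PP2-A5oe replicate 3, which left 11 lists in all. Heat shock genes were lower in 3 of 5 cases (adjusted p = 0.0346, or adjusted p = 0.131 with an estimated correlation) and unfolded protein response genes in 5 of 12 (0.0499, or adjusted p = 0.268 with an estimated correlation), both counts the same adjusted over the list alone. Clock genes were higher in 5 of 12 cases (5 adjusted over the list alone, 0.0346, or adjusted p = 0.227 with an estimated correlation), with GI at 1.05 ± 0.20 and CDF1 at 0.48 ± 0.06. Abscisic acid genes were higher in 5 of 10 cases and lower in 1, as adjusted over the list alone (0.0423, or adjusted p = 0.138 with an estimated correlation), with NCED3 at 0.87 ± 0.09. Senescence genes were lower in 4 of 8 cases and higher in 1, as adjusted over the list alone (0.0499, or adjusted p = 0.179 with an estimated correlation), with NAC092 (NAC6) at -1.34 ± 0.14. In glucosinolate breakdown 1 of 8 genes was lower and 1 higher, as adjusted over the list alone (0.0381, or adjusted p = 0.33 with an estimated correlation); NIT2, a nitrilase gene, differed by -2.08 ± 0.09.

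Immune, touch, sulphur, jasmonate biosynthesis, abscisic acid and aliphatic glucosinolate lists passed in the mean of both lines and in each line by itself, in the same direction, also with an estimated correlation. These tests are not independent. They share the same Col-0 libraries, and the mean is made from both lines, so a trait of the Col-0 plants would move each of them alike. The indolic glucosinolate list passed likewise, but was lost in PP2-A5oe with an estimated correlation (adjusted p = 0.0594). Of 21 immune genes 13 rose in the mean of both lines, with a median log2 fold change of 0.57 and WRKY53 at 2.96 ± 0.12. All 17 touch and wound genes rose, with a median of 1.79, and 7 of 8 sulphur starvation genes, with a median of 0.81. Aliphatic glucosinolate genes fell in 12 of 20 cases, with MYB29 at -1.12 ± 0.10, and indolic glucosinolate genes rose in 8 of 14, with CYP83B1 at 0.73 ± 0.05.

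A call on the mean of both lines against Col-0 can rest on 1 line. It was made for 3751 genes, while 1826 genes were called in the same direction in each line. Of the 3751, 2112 were higher and 1639 lower (411 and 57 with a 2-fold change); with upper-quartile scaling 1836 of 4039 were higher and 2203 lower. In 20.5% of tested genes the 6 and 3 replicates did not overlap, where chance gives 2.38%. Adjusted over the list alone, 13 immune genes (adjusted p = 2.82e-19), 17 touch and wound genes (3.93e-71), 7 sulphur genes (1.31e-14) and 8 indolic glucosinolate genes (6.84e-08) rose, and 13 aliphatic glucosinolate genes (6.19e-10) fell. Salicylic acid genes rose in 16 of 25 cases (17 adjusted over the list alone, adjusted p = 1.13e-11) and jasmonate biosynthesis genes in 9 of 17 (9 adjusted over the list alone, adjusted p = 1.92e-06). Jasmonate and ethylene branch genes rose in 7 of 9 cases (7 adjusted over the list alone, adjusted p = 5.55e-05), and abscisic acid genes in 7 of 10 with 1 fall (the same adjusted over the list alone, adjusted p = 5.53e-05). In PP2-A5oe by itself the salicylic acid list (adjusted p = 0.076), the jasmonate and ethylene branch (0.187) and the phosphate list (0.585) did not pass. Clock genes rose in 7 of 12 cases and 1 fell (7 higher and 2 lower adjusted over the list alone, 1.41e-05), and cold genes rose in 7 of 11 and 1 fell (the same adjusted over the list alone, 2.84e-08), although the cold list did not pass in pp2-a5 by itself. These 11 of 15 lists held with an estimated correlation. The other 4 did not. Photosynthesis genes were lower in 23 of 34 cases (25 adjusted over the list alone, adjusted p = 3.21e-06, but adjusted p = 0.342 with an estimated correlation). Phenylpropanoid genes were higher in 6 of 11 cases (6 adjusted over the list alone, adjusted p = 0.00203, but adjusted p = 0.166 with an estimated correlation). Phosphate genes were higher in 4 of 8 cases and lower in 1, as adjusted over the list alone (adjusted p = 0.00683, but adjusted p = 0.166 with an estimated correlation). Jasmonate signalling genes were higher in 6 of 14 cases and lower in 1 (7 and 2 adjusted over the list alone, adjusted p = 0.00796, but adjusted p = 0.0722 with an estimated correlation). Root tissue markers were higher in 4 of 5 cases (5 adjusted over the list alone, median 0.96), but the list did not pass (adjusted p = 0.0685, or 0.00019 with directional fry).

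Among the largest rises of the mean, AT5G21960 was at least 23.5-fold higher than in Col-0, with 135 of its 145 counts from PP2-A5oe. AT1G26250, with 177 of its 225 counts from pp2-a5 (ratio 110, interval 19.5 to 4350), and PDF1.2b (30, 8.12 to 250), AT1G26240 (29.7, 5.14 to 1190) and AT5G38910 (27.3, 4.70 to 1100) had 1 or 2 counts in Col-0. AT4G08093 (-4.21 ± 0.51), RNS1 (-2.36 ± 0.36), GSTU3 (-2.07 ± 0.25), PP2-A8 (-1.97 ± 0.35) and AT2G05914 (-1.82 ± 0.24) had the largest falls. Across the 13975 tested genes, the log2 fold changes of PP2-A5oe and of pp2-a5 against Col-0 had a Pearson r of 0.627 and a Spearman rho of 0.660; genes are not independent replicates. Both comparisons used the same 3 Col-0 libraries, which could not be split, and simulated unchanged groups with shared controls gave a mean r of 0.506 and a mean covariance of 0.0174, against an observed covariance of 0.141. Of the called genes 1109 were higher in both lines, where 249.3 were expected from independent calls, and 717 were lower in both, where 124.4 were expected; shared controls add to this excess by an amount that these samples cannot give. Opposite calls numbered 26 genes higher in PP2-A5oe and lower in pp2-a5 (171.6 expected) and 37 with the reverse pattern (180.7 expected).

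**Figure D4:**
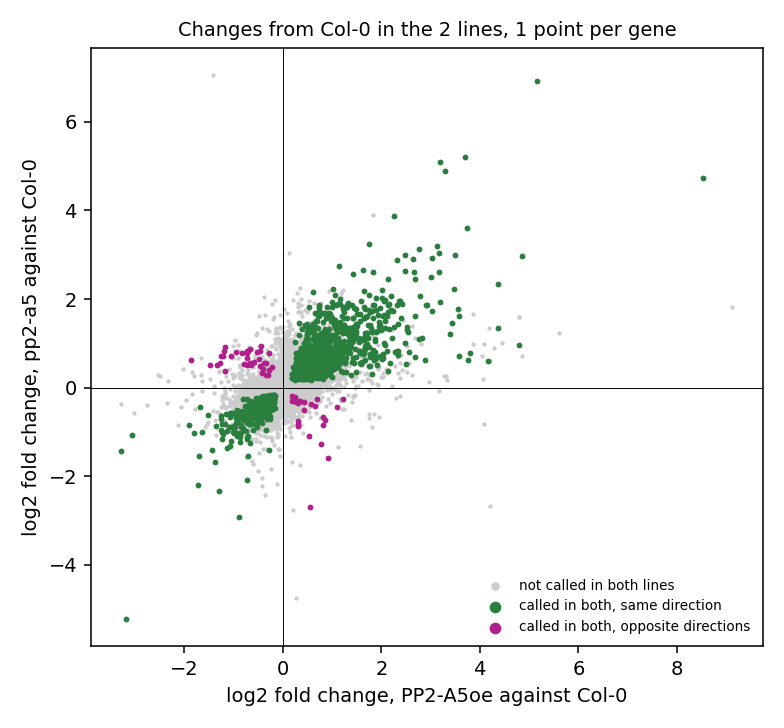
Log2 fold change of PP2-A5oe against Col-0 (x axis) and of pp2-a5 against Col-0 (y axis) for the 13975 tested genes; points are genes, green where called in both lines in the same direction, magenta where called in opposite directions, and grey otherwise. Genes called in both lines lie mostly along the diagonal, with 1109 higher and 717 lower in both.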

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

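The tests on the touch and wound genes below were all chosen after the result was seen. Gene lists were singled out here where the effect against Col-0 differed between PP2-A5oe and pp2-a5 by the direct test between the lines, with preset and with estimated correlation. In PP2-A5oe relative to pp2-a5 the median log2 fold change was 1.79 for touch and wound genes, 2.17 for cold genes, 0.85 for iron deficiency genes and 0.49 for sulphur starvation genes. It was -0.74 for salicylic acid genes, -1.17 for the jasmonate and ethylene branch, -1.22 for camalexin genes and -0.81 for phosphate starvation genes. Root tissue markers, with a median of 1.23, passed with the preset correlation (adjusted p = 0.00445) but not with an estimated one (adjusted p = 0.0603). Opposite calls against Col-0 were made for 63 genes. Each was also called between the lines, which adds no support, as opposite changes from the same Col-0 libraries add up in that comparison.

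The touch and wound genes stood out by size: their mean log2 CPM was 6.14 to 6.19 in the PP2-A5oe libraries, 4.18 to 4.32 in pp2-a5 and 3.31 to 3.57 in Col-0. Handling that differed from library to library is argued against, since the 3 PP2-A5oe libraries spanned only 0.05 on that scale while their mean lay 2.73 above Col-0. Handling or a harvest order shared by all PP2-A5oe plants would give the same picture as the genotype: the lowest PP2-A5oe library lay 1.82 above the highest other library, and the groups and the harvest cannot be told apart without harvest records. A different time of day at harvest also stays open, as GI, a clock gene, differed by 1.05 on the log2 scale between the lines. All 5 of 12 clock genes called there were higher in PP2-A5oe, while a shift in phase predicts changes both ways. The phases of the 12 tested genes were not compared. Against Col-0, 7 of 12 clock genes were called higher in PP2-A5oe and 0 lower, or 8 and 0 adjusted over the list alone. In pp2-a5 against Col-0, 5 were called higher and 0 lower, or 6 and 3 adjusted over the list alone. An effect of the genotype stays open and was not tested apart from these, and the list also rose in the mutant pp2-a5 (13 of 17 genes, median 0.71).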

How the results depend on the processing

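No called named gene and no list past its test passed in the opposite direction under any alternative. The balance of higher and lower calls against Col-0 did turn with upper-quartile scaling. The 3 alternatives chosen after seeing the data were genes with 1 annotated transcript, entries of a locus kept separate, and a fit without the pair of libraries with the highest mitochondrial share. Genes called at the reported setting that were called again made up 72.9% to 99.9% when 1 library was left out, and none of the reported calls turned to the opposite direction in any alternative. With DESeq2 this share was lower, at 71% in PP2-A5oe, 67.5% in pp2-a5, 65.9% between the lines and 70% for both lines. Its calls numbered 2505, 1975, 1179 and 2647 in that order. Leaving out 1 library gave 2818 to 3675 calls in PP2-A5oe, 2255 to 3145 in pp2-a5, 1342 to 2161 between the lines and 2859 to 3789 for both lines, each highest without Col-0 replicate 3. A 2-fold threshold left 585, 471, 395 and 468 calls in these comparisons and 207 genes called in the same direction in both lines. An adjusted p under 0.01 left 1887 calls in pp2-a5, 1174 between the lines and 1158 in the same direction; both thresholds are stricter by construction. DESeq2, run without the filter on low counts, called 1179 genes between the lines and gave an r of 0.566 for the overlap of the lines. The edgeR fit without a filter gave 0.554, against 0.627. Both lower values thus include low-count loci that are left out of the 0.627, and a further cause was not tested. The 63 genes called in opposite directions in the 2 lines became 40 with DESeq2 and 37 at an adjusted p under 0.01, and edgeR called 0 with a 2-fold threshold; the cause of the DESeq2 count was not tested. With the replicate block the calls were 3185, 2575, 1571 and 3392, with 1622 in the same direction and an r of 0.627. List calls with it were 13, 15, 16 and 15, against 13, 17, 17 and 15; jasmonate signalling and phenylpropanoid genes no longer passed in pp2-a5, nor unfolded protein response genes between the lines. The replicate numbers did not pair the libraries, whose residual correlations within a number ran from -0.18 to 0.062. Upper-quartile scaling lowered the share of higher calls to 49.7% in pp2-a5, to 45.5% for both lines and from 58.0% to 46.1% in PP2-A5oe, where the median log2 fold change of all genes was then -0.064. With an estimated correlation 8 lists passed in PP2-A5oe, 12 in pp2-a5, 8 between the lines and 11 for both lines. Directional fry called 23 lists in PP2-A5oe and 23 for both lines, and mixed fry called 32 in PP2-A5oe, 29 in pp2-a5, 29 between the lines and 32 for both lines; fry tests no list against other genes. Lists past the test between the lines numbered 11 to 17 when 1 library was left out, with 11 without PP2-A5oe replicate 3. Over all alternatives, 2773 of 2978 list tests kept their side of the threshold, 124 passed where the reported test had not and 81 no longer passed. Of the 124, fry gave 32 (directional) and 60 (mixed), which answer another question than camera. Of 7649 tests of genes picked by the rule for named genes, 141 no longer passed: 92 without a library, 20 with DESeq2, 18 without the pair of libraries with the highest mitochondrial share, 6 with the replicate block and the rest in other alternatives. Among the calls of these genes given in the text, that of WRKY75 in PP2-A5oe was the only one to end. In addition, 181 of 2686 counts of called list members moved by over 1.5 times. Alternatives for the PP2-A5 transcript were not run, as it was not analysed here, and a fit of the compared groups alone has no separate value for both lines. In simulated data at this depth, with 50 genes changed per fold, 2-fold changes were recovered in 76% to 88% of cases and 1.5-fold changes in 64% to 76%. The adjusted p depends on how many genes change, and far more were called in the data. The simulated rates therefore need not hold for the real comparisons. In the same simulation, genes left unchanged made up 6.12% of the calls in PP2-A5oe (9 genes), 9.82% in pp2-a5 (16 genes) and 4.35% between the lines (6 genes).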

Other observations

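The tests on AT1G03240 and AT1G03230 were chosen after the result was seen, as was the interval of rho below, while the other tests on transcript numbers and on splits of the libraries were not. Relatives of PP2-A5 in the PP2-A lectin family did not pass with camera in either line. In PP2-A5oe 2 of 9 rose and 3 fell (the same adjusted over the list alone, adjusted p = 0.725), and in pp2-a5 4 of 9 fell (4 adjusted over the list alone, median -0.20, adjusted p = 0.0537). With directional fry the list was lower in pp2-a5 (adjusted p = 0.0113) but did not pass in PP2-A5oe (adjusted p = 0.743). PP2-A8 fell from 3.25 ± 1.44 CPM in Col-0 to 0.985 ± 0.462 in PP2-A5oe and 0.698 ± 0.185 in pp2-a5 (SD, n = 3), and PP2-A11 fell by 0.64 on the log2 scale in pp2-a5. Ethylene genes rose in 5 of 17 cases and fell in 2 in PP2-A5oe (7 and 5 adjusted over the list alone, adjusted p = 0.347); ACS6, an enzyme gene of ethylene synthesis, rose by 2.13 ± 0.09 on the log2 scale (SE). Senescence genes rose in 2 of 8 cases and fell in 5 in PP2-A5oe, as adjusted over the list alone (adjusted p = 0.347), and NAP, a senescence regulator, rose by 1.33 ± 0.11 in PP2-A5oe and 1.86 ± 0.10 in pp2-a5. In glucosinolate breakdown, ESM1 fell from 2142 ± 75.9 CPM in Col-0 to 1235 ± 54.8 in PP2-A5oe and 1293 ± 36.6 in pp2-a5 (2 annotated transcripts), and NIT2 fell by 1.17 in PP2-A5oe but rose by 0.91 in pp2-a5 on the log2 scale. That list did not pass against Col-0 (3 of 8 rose and 3 fell in PP2-A5oe, also adjusted over the list alone, adjusted p = 0.456).

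Other lists that did not pass in PP2-A5oe against Col-0 were flavonoid genes (7 of 16 rose and 1 fell, 7 and 2 adjusted over the list alone, adjusted p = 0.138) and reactive oxygen genes (6 of 14 rose and 5 fell, also adjusted over the list alone, 0.803). Protease inhibitor genes (1 of 8 rose and 2 fell, also adjusted over the list alone, 0.347) and unfolded protein response genes (1 of 12 rose and 3 fell, 1 and 5 adjusted over the list alone, 0.347) did not pass, with KTI1 at -1.24 ± 0.14 and BZIP60 at 0.77 ± 0.09. Heat shock (1 of 5 fell, 1 adjusted over the list alone, 0.487), auxin (3 of 15 rose and 3 fell, 4 and 4 adjusted over the list alone, 0.928) and cell cycle genes (1 of 14 fell, 0 adjusted over the list alone, 0.295) did not pass. Floral transition genes (2 of 5 rose and 1 fell, 3 and 1 adjusted over the list alone, 0.78) and phloem markers (1 of 9 rose and 1 fell, also adjusted over the list alone, 0.585) did not pass, nor did guard cell and trichome markers (2 of 8 fell, 2 adjusted over the list alone, 0.306). Of 4 flower organ markers edgeR called 0, with 1 at an unadjusted p under 0.05 and 0 by DESeq2 or limma-voom. Median, mean and test differed in sign for auxin genes in PP2-A5oe (0.14, 0.11, lower) and in pp2-a5 (0.02, -0.01, lower), for PP2-A lectins (0.05, -0.05, lower) and floral genes (0.35, -0.02, higher) in PP2-A5oe. Between the lines they differed for jasmonate biosynthesis (0.09, -0.11, higher) and floral genes (0.08, -0.08, higher), and for both lines for heat shock (-0.17, -0.04, higher), auxin (-0.06, 0.05, lower) and protease inhibitor genes (0.01, 0.00, lower). None of these 9 tests passed.

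Of the genes called in opposite directions in the lines, NIA1 and NPC4 were chosen here after their values were seen, and no theme of these genes was tested. QQS stood at 36.3 ± 2.80 CPM in PP2-A5oe, 24.5 ± 2.95 in Col-0 and 3.77 ± 0.189 in pp2-a5. The nitrate reductase gene NIA1 changed by 0.30 ± 0.06 in PP2-A5oe and -0.82 ± 0.06 in pp2-a5 on the log2 scale, and the phospholipase gene NPC4 by -1.28 ± 0.17 and 0.55 ± 0.13. SPX3 changed by -1.87 ± 0.27 and 0.62 ± 0.18. Of 1607 genes called against Col-0 in PP2-A5oe and not in pp2-a5, 589 were called between the lines, and of 1013 called in pp2-a5 alone 386 were. HEI10, which overlaps MRD1 and was chosen after its values were seen, went from 7.2 ± 0.856 CPM in Col-0 to 2.15 ± 0.246 in pp2-a5.

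AT1G03240 and AT1G03230, which lie 532 bases apart, both rose in PP2-A5oe: AT1G03230, chosen after its values were seen, went from 56.9 ± 3.73 to 218 ± 2.29 CPM. Reads of AT1G03230 counted for AT1G03240 at a fixed share are argued against, since the share in PP2-A5oe (204 to 3783 counts) would give 113 AT1G03240 counts in the other 6 libraries, and 1 was seen. A change at one place on the chromosome may account for the pair and stays open: edgeR called 0 of 6 tested flanking genes (10 annotated), with 1 at an unadjusted p under 0.05 and 0 called by DESeq2 or limma-voom. A change limited to the pair and separate changes of each gene would both give this, and no insertion site was analysed here.

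Genes with several annotated transcripts had few counts: 42.8% of protein-coding loci with 1 transcript had under 50 counts over the 9 libraries, against 51.3% with 2 and 63.8% with 3 or more. Reads shared by the transcripts of a gene may have been left out of the counts. The count and the share of bases in 1 transcript alone had a Spearman rho of 0.0572 over 5958 loci (bootstrap interval 0.0318 to 0.083), below the 0.1 set beforehand. This low rho cannot exclude such a loss, as counts varied widely at a similar share (quartiles 0 and 705 in the lowest class). A whole or partial loss stays open: rho was above 0 (permutation p = 1e-04, the smallest these permutations give), and the median count was 24, 45, 70 and 56.5 from the lowest to the highest class of that share. Of the 294 loci with 2 entries, 292 have 2 or more annotated transcripts. The gene models behind the counts are not given, and the transcript numbers are those of the TAIR10.1 annotation, which may differ from them. A lower expression of such genes could also be the source and cannot be told apart: loci with 2 transcripts and more than 0.5 of their bases in 1 transcript alone had a median of 56.5 counts, against 163 for loci with 1 transcript.

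In fits of the compared groups alone, the real grouping gave 3217 calls in PP2-A5oe, 2711 in pp2-a5 and 2069 between the lines, and the highest count among the other splits was 0 in each; with 10 splits of 6 libraries, 1 of them real, no share under 0.05 can be reached. For both lines against Col-0 in a 2-group fit, 1 of 84 splits, the real one with 2365 calls, gave as many. This share is under 0.05, but it shows only that libraries of the same group resembled each other. The splits cannot tell genotype from another difference between whole groups, such as growth or harvest. The highest other split, with 974 calls, set PP2-A5oe against the rest, and the split that set pp2-a5 apart gave 460; splits that mixed the groups gave at most 0.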
